A study of Homo sapiens with 3 samples.

How the data were processed

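Contacts between genomic sites held by cohesin were measured by HiChIP in MB157 cells, an established triple-negative breast cancer cell line. HiChIP joins DNA ends that lie close together in the nucleus, pulls down the joined fragments with an antibody and sequences both ends of each fragment; here the antibody was against SMC1a, a subunit of the cohesin ring. There were 3 libraries and 1 per group: untreated cells, cells kept for 72 hours in 1 uM of compound E, a gamma-secretase inhibitor (GSI) that blocks the release of active Notch, and cells given the same GSI treatment, washed and then grown for 3 days in medium with DMSO (washout). Groups were taken from the drug treatment label of each library; the untreated library's file is named for DMSO while its label says untreated. No group had a replicate, so the spread between cultures is unknown, no test between conditions was run and no p-value is given. Each group was its own library, so batch and treatment cannot be told apart.

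Chromatin was cut with MboI and libraries were made with Tn5 and sequenced as paired ends, per the labels' protocols. HiC-Pro, Juicer 1.7.6 and MACS were used on build hg19, per the submitters' processing notes; the names of the files point to MACS for the untreated and MACS2 for the other libraries, and whether calling differed is not given in the sources used here. Which step each tool served, the caller of the pairs, its distance model and its thresholds are not given in the sources used here. The deposited files hold pairs of genomic intervals (anchors) with the number of contacts between them as a whole-number count, which the authors did not scale. Every pair was listed from both of its anchors and was counted here once. All pairs lay within 1 chromosome and within 2 Mb, and the smallest count was 2. The smallest listed count depended on distance: below 5 kb it was 8 in the untreated, 6 in the GSI and 7 in the washout library, and between 1000 and 2000 kb it was 2 in all 3. A pair missing from a list therefore had too few contacts to be listed or had an anchor that was not called, and was not measured as 0. Anchors had different borders in each library, as separate calling in each library would give.

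Total listed contacts were 3284437 in the untreated, 2146115 in the GSI and 6487075 in the washout library. These totals count listed pairs only and are not the sequencing depth of the libraries, which was not analysed here. Counts were scaled per 1000000 listed contacts of the library. Log2 ratios carried a pseudocount of 1 count in the GSI library, which is 0.466 on this scale, unless stated as ratios without it. Because anchors differed, they were assigned by their midpoints to bins of 25 kb, and pairs of anchors were summed over pairs of bins. The bin width was chosen after the files had been seen. Bins with at least 50 contacts in either library and all bin pairs in either list entered each comparison, and a 2-fold difference was the size counted. Windows of 1 Mb, assigned by the midpoint between the anchors, with at least 200 contacts in 1 of the compared libraries and a 4-fold difference were added after the data had been examined. Minimum counts were of unscaled contacts, so bins and windows entered at a lower scaled level through the library with more listed contacts. Sums over separately called anchors move with how much was called, so anchor numbers and lengths are given beside them. Intervals are 95% exact: Clopper-Pearson for shares, and conditional binomial for ratios of counts. They cover counting error only.

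Hubs were the bins above the 99th percentile of the number of partner bins, and connected groups were Leiden communities per chromosome weighted by contact count. Both used libraries thinned at random to the smallest total, with thinned counts below 2 removed. A simulation drew 3 libraries of the observed sizes from 1 pooled profile 20 times. It drew counts per bin pair, dropped those below 2, and modelled neither separate anchor calling nor the floor that depended on distance. The drawn counts were scaled by totals taken after counts below 2 were dropped, with the pseudocount unchanged. Other simulations drew libraries at the smallest total, for bins, for 100 kb bins and for pairs with shared anchors. Ratios were tested on simulated data for GSI against untreated with 52143 bins. Bins made 4-fold lower (85 bins, true log2 of -2) had a median log2 of -1.96, and 98.8% passed the 2-fold size. Of the 100 bins with a true log2 of 2, 100% passed, and of the 51958 bins left alike 0.0847% passed. These simulated bins carried counting error only, without separate anchor calling. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.

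The regions named were set by a rule fixed, with its minimum counts, before the data were examined; it was written for gene promoters or, without an annotation, bins, and the width of 25 kb was added after. For GSI against untreated and for washout against GSI, it took the 12 bins with the lowest and the 12 with the highest log2 ratio among bins with at least 50 contacts in either library. It also took the 5 lowest and 5 highest bin pairs for GSI against untreated among those with at least 20 contacts, at most 1 per 100 kb. Hubs, connected groups, chromosomes and windows outside this rule were named for their size after their values had been seen. Gene names, promoter contact per gene and gene lists fixed in advance were left out, since an annotation of build hg19 was not used here; regions are given by hg19 coordinates counted from 1. The alternatives tried were other scalings, thinning, a larger pseudocount, other minimum counts, distance limits, other bin widths and pairs with shared anchors. Median-ratio scaling took its factors only from the 53603 bin pairs (2.75%) listed in all 3 libraries. Being listed in the smallest list selects pairs with high counts there, so this scaling is not a neutral check.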

Results

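Cohesin-associated contacts were mapped in MB157 breast cancer cells with Notch signaling on (untreated), off (72 hours of the gamma-secretase inhibitor, GSI) and recovering (3 days after washout). The comparisons asked which long-range contacts between regulatory elements differ when Notch is switched off and which return after recovery. Each condition had 1 library, so every difference below is a difference between libraries and has no replicate check.

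The untreated list held 759964 pairs of anchors with 3284437 contacts, the GSI list 566927 pairs with 2146115 contacts, and the washout list 1567914 pairs with 6487075 contacts. The washout list thus had 3.02 times and the untreated list 1.53 times the contacts of the GSI list. Anchors numbered 454136 in untreated, 378578 in GSI and 594871 in washout, and covered 693, 557 and 974 Mb. The median pair had 3 contacts in all 3 libraries. Pairs with at least 20 contacts numbered 16153 in untreated, 4126 in GSI and 21755 in washout.

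Listed contacts in the GSI library spanned longer distances than in the untreated library when all pairs were counted. The median distance weighted by contacts was 281 kb in untreated, 410 kb in GSI and 346 kb in washout. Contacts of up to 20 kb made up 19.1% (95% interval 19.1 to 19.2) of the untreated, 14.7% (14.6 to 14.7) of the GSI and 13.5% (13.5 to 13.5) of the washout library. Between 1000 and 2000 kb the GSI share was 26.9%, against 22.4% in untreated and 22.8% in washout. From 500 to 1000 kb the shares were 16.7% in untreated, 18.8% in GSI and 19.1% in washout, and from 20 to 100 kb they were 14.5%, 12.2% and 14.2%. Counted over pairs without weights, the median distances were 827, 851 and 799 kb. With at least 5 counts per pair they were 115 kb in untreated, 105 kb in GSI and 141 kb in washout, so the order of untreated and GSI turned.

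**Figure D1:**
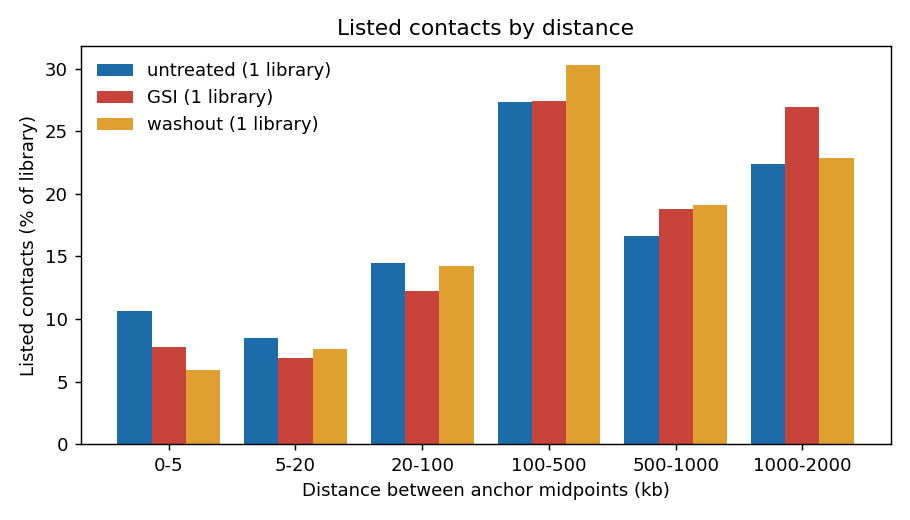
Share of listed contacts (% of the library, y axis) in 6 classes of distance between anchor midpoints (kb, x axis) for the untreated, GSI and washout libraries, 1 bar per library. The GSI bar is the highest between 1000 and 2000 kb (26.9%) and the untreated bar is the highest below 5 kb (10.7%).

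Most of the strongest anchors of each library overlapped anchors of the others. Of the untreated anchors with at least 50 contacts, 92.7% overlapped a GSI anchor and 99.1% a washout anchor. Of the GSI anchors of that strength, 98.6% overlapped an untreated and 99.7% a washout anchor. Of the washout anchors of that strength, 95.7% overlapped an untreated and 89.5% a GSI anchor. After a shift by 50 kb these shares were still 69.2% and 85.7% for untreated and 82.4% and 90.7% for GSI anchors. For washout anchors they were 78.0% and 70.8%. Part of the overlap thus comes from how densely anchors lie. Over anchors of any strength, 64.2% of those in untreated overlapped a GSI anchor, against 48.6% after a shift by 50 kb. Anchors overlapping both other libraries made up 60.6% of the untreated, 73.7% of the GSI and 45.8% of the washout anchors.

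Individual interactions were shared more often when they were strong. A bin pair counted as shared when both midpoints lay in the same 25 kb bins, and an anchor on an overlap of 1 bp, so their rates are not comparable. The lists covered 1948914 bin pairs of 25 kb, and 53603 of these (2.75%) were in all 3. Another 390305 were in untreated alone, 285703 in GSI alone and 913451 in washout alone. Untreated and washout shared 150796 that GSI lacked, GSI and washout shared 108143 that untreated lacked, and untreated and GSI shared 46913 that washout lacked. Of untreated bin pairs with 2 contacts 10.0% were listed in GSI, against 75.8% (95% interval 74.6 to 77.0) of those with at least 50; in the other direction these shares were 13.9% and 84.7% (82.6 to 86.7).

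Over all bin pairs, 15.7% of those in untreated were found in GSI and 20.3% of those in GSI in untreated. Libraries drawn from 1 common profile at the same sizes gave 38.9% and 59.8%. These draws had neither separate anchor calling nor the higher floor at short distance, so the gap does not measure a difference between conditions. The observed shares depended strongly on how near 2 pairs had to lie: allowing 1 bin of distance at both ends raised them to 58.8% and 69.3%, and bins of 5 kb lowered them to 2.75% and 3.67%.

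**Figure D2:**
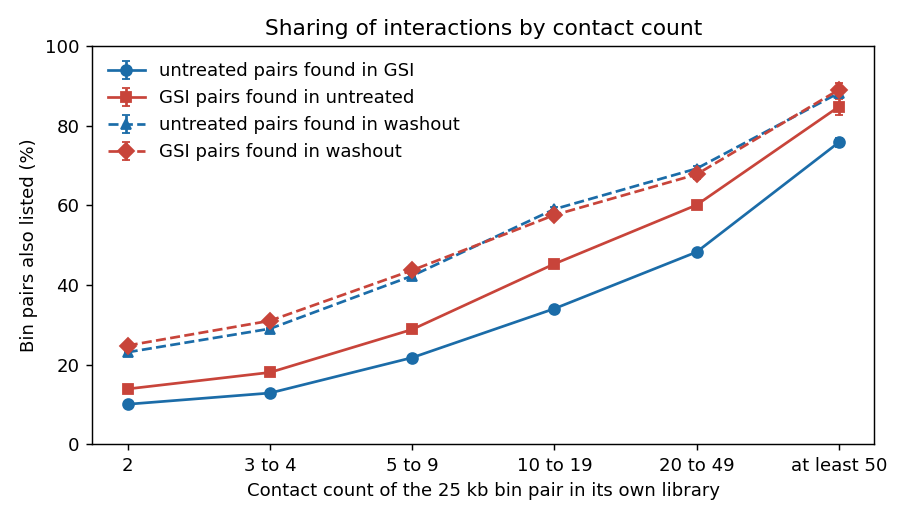
Share of 25 kb bin pairs that were also listed in another library (%, y axis) by their contact count in their own library (x axis), for untreated and GSI pairs, with 95% Clopper-Pearson intervals as bars. All 4 lines go up with the count, from 10.0% at 2 contacts to 75.8% at 50 or more for untreated pairs found in GSI.

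GSI against untreated asked which contacts were lower or higher with Notch off. The largest differences by chromosome were lower shares on chromosomes 22 and 15. Chromosome 22 held 0.379% of untreated contacts, 0.0617% of GSI contacts and 0.216% of washout contacts. The log2 ratio of GSI to untreated was -2.62 (95% interval -2.70 to -2.54). Chromosome 15 held 0.565%, 0.151% and 0.526%, a log2 ratio of -1.91 (-1.96 to -1.85). Chromosomes 11 (log2 ratio -0.67), 12 (-0.42) and 16 (-0.35) were also lower in GSI, and chromosomes 8 (0.46) and X (0.30) were higher. Chromosome 8 held 6.72% of untreated, 9.24% of GSI and 6.74% of washout contacts.

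Fewer anchors were listed in GSI on chromosomes 22 and 15. Chromosome 22 had 2431 anchors in untreated, 522 in GSI and 2381 in washout, and chromosome 15 had 4035, 1186 and 6084. Chromosomes 8 and X, with higher GSI shares, also had fewer anchors in GSI than in untreated (26718 against 27454 and 28981 against 32472). With pairs restricted to anchors overlapping in all 3 libraries, the GSI to untreated log2 ratio was -0.22 for both chromosome 22 and chromosome 15, and 0.21 for chromosome 8. This restriction leaves out by design every anchor that GSI lacked, so it does not show why the chromosomes differed. The signs given for these 7 chromosomes were the same under scaling by the median ratio, scaling within distance classes and thinning, but median-ratio scaling put X at 0.02 and chromosome 8 at 0.18.

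**Figure D3:**
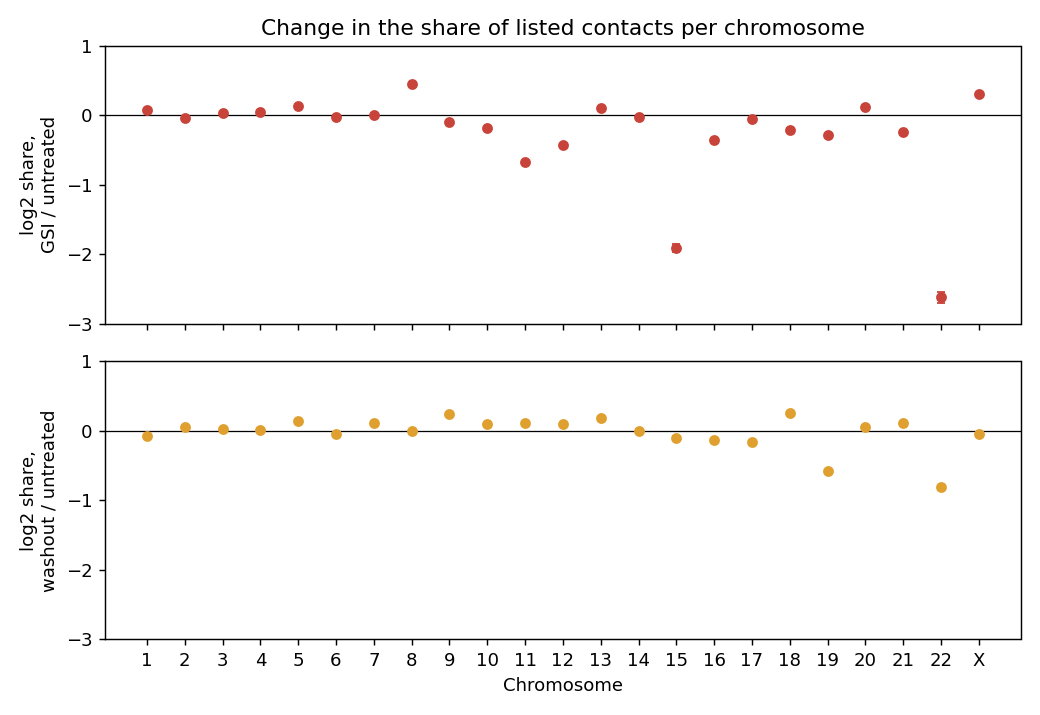
Log2 ratio of the share of listed contacts per chromosome (y axes) for GSI over untreated (top) and washout over untreated (bottom), 1 point per chromosome with 95% counting intervals, mostly smaller than the points. Chromosomes 22 and 15 lie at -2.62 and -1.91 in GSI and at -0.81 and -0.10 in washout.

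Part of the lower contact in GSI lay in long stretches of the genome. Of 2326 windows of 1 Mb, 195 were at least 4-fold lower in GSI than in untreated and 1 was at least 4-fold higher. The lower windows lay on 19 chromosomes: 24 of the 28 windows measured on chromosome 22, 21 of 53 on chromosome 15, 21 of 128 on chromosome 12, 16 of 74 on chromosome 17 and 13 of 50 on chromosome 19. None lay on chromosomes 6, 20, 21 or X. They formed 86 stretches, of which 25 were at least 3 Mb long, the longest of 13 Mb.

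The longest stretch ran from 28 to 41 Mb of chromosome 22 and held 5730 contacts in untreated, 345 in GSI and 6429 in washout. Scaled to library totals, GSI was 10.9 times below untreated (log2 ratio -3.44, 95% interval -3.60 to -3.28). From 40 to 48 Mb of chromosome 19 the contacts were 5156, 152 and 3892 (log2 ratio -4.47, -4.71 to -4.24). From 37 to 44 Mb of chromosome 17 they were 3683, 90 and 5435 (log2 ratio -4.74, -5.06 to -4.44). From 46 to 52 Mb of chromosome 12 they were 3287, 199 and 5285 (log2 ratio -3.43), and from 24 to 29 Mb of chromosome 1 they were 3330, 202 and 5462 (also -3.43). From 39 to 43 Mb of chromosome 15 they were 1655, 30 and 2393 (log2 ratio -5.17, -5.74 to -4.65).

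Together the 195 windows held 3.34% of untreated, 0.405% of GSI and 2.35% of washout contacts. A window had a median of 85 anchors over 113 kb in untreated, 14 anchors over 15.8 kb in GSI and 106 anchors over 138 kb in washout. The other windows had a median of 207 anchors in untreated, 177 in GSI and 267.5 in washout. In the 195 windows, contacts per 1000000 listed, for each 100 kb of anchor, were 139 in untreated, 92.9 in GSI and 82.7 in washout. In the other windows they were 145, 181 and 104. With only anchors overlapping in all 3 libraries, 0 windows were 4-fold lower in GSI. That restriction leaves out the anchors GSI lacked by design, so the 0 does not separate lower contact from anchors that were not called. File names point to MACS for the untreated and MACS2 for the GSI and washout libraries, and the effect of this on the anchors is unknown.

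**Figure D4:**
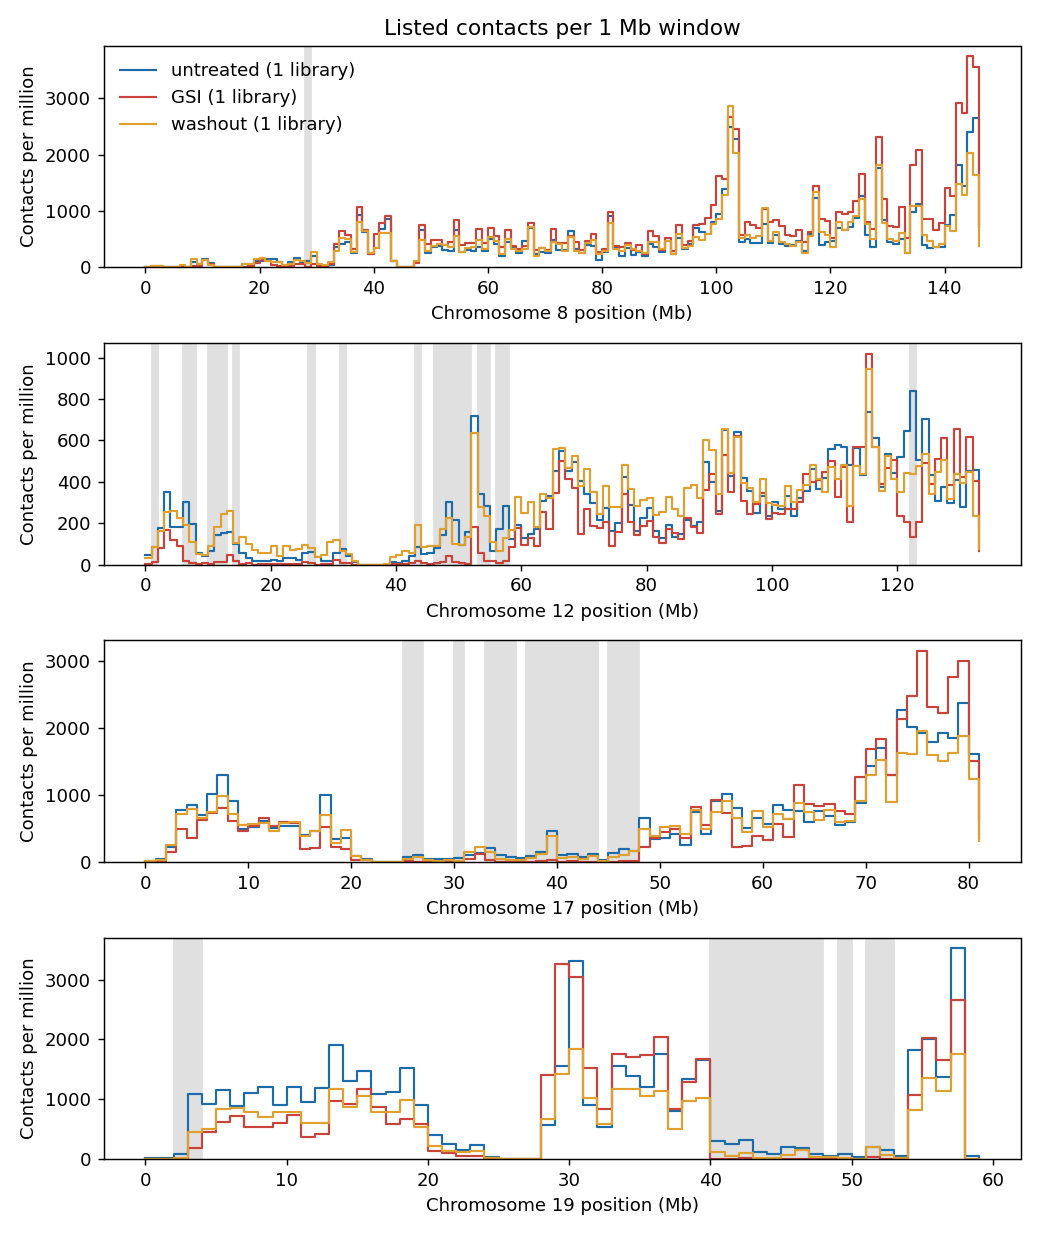
Contacts per 1000000 listed contacts in 1 Mb windows (y axes) along chromosomes 8, 12, 17 and 19 (x axes, Mb, hg19) for the untreated, GSI and washout libraries; grey bands mark windows at least 4-fold lower in GSI than in untreated. The GSI line lies near the baseline from 40 to 48 Mb of chromosome 19 and from 37 to 44 Mb of chromosome 17, where the untreated and washout lines do not.

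Among bins of 25 kb, 9422 of 51224 (18.4%) were at least 2-fold lower in GSI than in untreated and 7437 (14.5%) were at least 2-fold higher. The 12 lowest bins had 193 to 377 contacts in untreated and no listed contact in GSI, and 9 of them lay in the 195 windows. Adjoining bins at chromosome 15:41150001-41175000 and 15:41175001-41200000 had 377 and 325 contacts in untreated, none listed in GSI, and 188 and 204 in washout. At 11:67075001-67100000 the counts were 309 in untreated and 106 in washout, with 78 GSI contacts listed in the bins on either side. At 12:54675001-54700000 they were 220 in untreated and 145 in washout. At 22:50350001-50375000 there were 194 in untreated and none listed in either GSI or washout.

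The 12 highest bins lay on 7 chromosomes and outside the 195 windows. The bin at 8:119975001-120000000 had 9 contacts in untreated, 167 in GSI and 87 in washout (log2 ratio of GSI to untreated without pseudocount 4.83, 95% interval 3.87 to 5.98). The bin at 7:150525001-150550000 had 9, 108 and 217 (4.20, 3.22 to 5.37), that at X:39500001-39525000 had 9, 106 and 110 (4.17, 3.19 to 5.34), and that at X:54950001-54975000 had 17, 147 and 183 (3.73, 3.00 to 4.54). The split between lower and higher bins turned in thinned libraries, with 5997 lower and 8402 higher, where weak pairs were also dropped from the deeper lists; it kept its direction under median-ratio scaling, with 12655 and 4527.

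Bin pairs named as the most different were mainly short-range. All had none listed in untreated or in GSI, so their rank followed the count in the other library. Counts were higher at short distance (untreated median 19 below 5 kb and 2 from 1000 to 2000 kb), so short range was largely built in. The 5 lowest in GSI had 198 to 267 contacts in untreated and none listed in GSI. Within 19:3700001-3725000 there were 267 contacts in untreated and 85 in washout; allowing 1 bin on each side, the 3 libraries had 536, 32 and 319. Between 8:142375001-142400000 and 8:142425001-142450000 there were 202 in untreated, none listed in GSI and 104 in washout, and 374, 119 and 232 with 1 bin on each side. Within 19:39675001-39700000, GSI had 112 and washout 92 contacts with none listed in untreated, and with 1 bin on each side the counts were 12 in untreated, 214 in GSI and 194 in washout. Between 20:52400001-52425000 and 20:52425001-52450000, GSI had 126 and washout 250 with none listed in untreated, but the surrounding bins brought untreated to 158, GSI to 228 and washout to 585. Counts of 0 for a pair thus partly reflected where anchor midpoints lay.

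Over all bin pairs in either list, 547343 were at least 2-fold lower in GSI and 405803 higher. Libraries drawn from 1 profile gave 390311 lower and 184937 higher on average, so an excess of lower pairs does not by itself show a difference. Most had few contacts, and thinning the libraries turned the split to 368854 lower and 422650 higher. Among bin pairs with at least 20 contacts, 15023 were lower and 5025 higher, but this unscaled minimum favours pairs strong in untreated, which had more listed contacts. In the 53603 bin pairs listed in all 3 libraries the median log2 ratio of GSI to untreated was 0.35. Being listed in the smaller GSI list selects pairs with high counts there, so a raised ratio was partly built in.

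Washout against GSI asked what differed once Notch could recover. The stretches that were low in GSI were higher in washout. Of 2599 windows of 1 Mb, 313 were at least 4-fold higher in washout than in GSI and 0 were at least 4-fold lower. Under median-ratio scaling these counts were 616 and 0. Of the 195 windows low in GSI, 159 were at least 4-fold higher in washout, with a median log2 ratio of 2.79 (quartiles 2.13 and 3.58). These windows were chosen for low GSI contact and are set here against that same library, so part of this rise follows from the choice. Between 37 and 44 Mb of chromosome 17 the log2 ratio of washout to GSI was 4.32 (95% interval 4.02 to 4.64), and between 39 and 43 Mb of chromosome 15 it was 4.72 (4.20 to 5.29), 26.4 times above GSI. Chromosome shares on 22 and 15 were higher by log2 ratios of 1.81 and 1.80, and that on chromosome 8 was lower (-0.45); median-ratio scaling turned chromosome 8 to 0.47.

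Among bins, 16980 of 75718 (22.4%) were at least 2-fold higher in washout than in GSI and 6072 (8.02%) lower. The 12 highest bins had 246 to 275 contacts in washout and none listed in GSI, and 7 lay in the windows low in GSI. At 19:46525001-46550000 untreated had 183 and washout 270 contacts, at 11:69025001-69050000 they had 153 and 266, and at 7:75750001-75775000 they had 115 and 275. At 12:22475001-22500000 washout had 255 contacts against 19 in untreated. Among the lowest, the bin at 20:49475001-49500000 had 522 contacts in untreated, 407 in GSI and 95 in washout (log2 ratio of washout to GSI without pseudocount -3.69, -4.03 to -3.37), that at 19:57000001-57025000 had 302, 395 and 71 (-4.07, -4.46 to -3.70), and that at 1:201575001-201600000 had 64, 230 and 52 (-3.74, -4.20 to -3.30). In thinned libraries the split of bins turned to 3881 higher and 7891 lower, and with median-ratio scaling it was 39985 and 565. Bin pairs split almost evenly, with 412821 higher and 391472 lower in washout. This split rests on the 2-fold edge, since 3 washout contacts against none listed gave 1.99-fold and were not counted. Without the top 0.1 percent of bins 671283 were higher and 388205 lower, and median-ratio scaling gave 684653 and 345180. Draws from 1 profile gave 450516 and 184887 on average. Their totals were taken after counts below 2 were dropped, which moves this edge, so they are not a like reference.

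Washout against untreated asked how near contacts came to their starting level. Most stretches low in GSI were close to untreated after washout: 144 of the 195 windows lay within 2-fold, with a median log2 ratio of -0.57. Elsewhere 2170 of 2414 windows lay within 2-fold. Washout was above untreated in 1504 of the 2414, against 42 of the 195. From 37 to 44 Mb of chromosome 17 the log2 ratio was -0.42 (95% interval -0.48 to -0.36), and from 46 to 52 Mb of chromosome 12 it was -0.30 (-0.36 to -0.23). Chromosome 19 from 40 to 48 Mb stayed lower (-1.39, -1.45 to -1.33), as did chromosome 22 from 28 to 41 Mb (-0.82, -0.87 to -0.76). Median-ratio scaling moves ratios of large counts by 0.64, which turns -0.57, -0.42 and -0.30 positive, so how near washout came to untreated depended on the scaling. That scaling rests only on pairs listed in all 3 libraries, a selection that favours high counts in the smaller lists.

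Of all 2609 windows, 3 were at least 4-fold lower in washout than in untreated and 38 at least 4-fold higher. The lower ones were 41 to 42 Mb and 43 to 44 Mb of chromosome 19 and 24 to 25 Mb of chromosome 22, all low in GSI as well. Under median-ratio scaling 0 windows were 4-fold lower and 122 were 4-fold higher, so the calls of these 3 rest on the scaling. The higher ones included 83 to 84 Mb of chromosome 9 with 12 contacts in untreated, 13 in GSI and 618 in washout, 82 to 83 Mb of the same chromosome with 65, 87 and 1478, and 11 to 12 Mb of chromosome 4 with 32, 131 and 414. By chromosome, the share was lower in washout on 22 (log2 ratio -0.81) and 19 (-0.58; 0.06 under median-ratio scaling). Bin pairs split into 470587 lower and 390360 higher in washout. Draws from 1 profile gave 191925 and 346437 on average, but their smaller totals move the 2-fold edge, so they are not a like reference. Median-ratio scaling, under which 3 washout contacts against none listed passed 2-fold, turned the split to 450838 and 653989. Bins went the other way, with 5409 of 76599 at least 2-fold lower and 12460 higher, which thinning turned to 5102 and 3195.

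Contacts lower with Notch off and higher after recovery were counted against the opposite order. Among bins, 10560 of 76724 were at least 2-fold lower in GSI than in untreated and at least 2-fold higher in washout than in GSI, against 3159 with the opposite order. Libraries drawn from 1 profile also gave more of the former (up to 2419) than of the opposite (up to 17), and thinning turned the observed order to 3297 against 3975, a ratio of 0.829 against 1.07 to 3.63 in equal draws from 1 profile. Thinning changed the totals and also dropped weak pairs from the deeper lists only, so the turn cannot be put down to depth alone. Among bin pairs with at least 20 contacts the counts were 13411 and 4331, a ratio of 3.10, which fell to 1.37 after thinning. Among all bin pairs the order was the other way, with 80213 lower and then higher against 337103 higher and then lower; this count depends on listing and the pseudocount, since 2 GSI contacts against none listed passed the 2-fold size while 3 washout contacts against none listed reached 1.99-fold. With at least 5 counts the order was 64841 against 67745. Libraries drawn from 1 profile gave a ratio between 1.47 and 1.49 over all bin pairs. Their totals were taken after counts below 2 were dropped, which moves that 2-fold edge, so this is not a like reference. For bin pairs with at least 20 contacts the draws gave a ratio between 1.73 and 2.20. At equal totals that ratio was between 1.15 and 2.15, which includes the thinned value. The draws at the observed sizes held only 683 and 356 such pairs on average, against the 13411 and 4331 observed, so a like ratio says little. Among pairs of 100 kb bins with at least 20 contacts the ratio was 3.21, against 12.5 to 18.0 from 1 profile. The ratio expected without change thus depended strongly on the setting. Both comparisons share the GSI library, whose chance values enter each count.

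Bins with many partners were partly the same in all conditions. After thinning, 813 bins in untreated, 861 in GSI and 948 in washout were hubs, and 158 were hubs in all 3, of which 31 lay on chromosome 8 and 30 on chromosome 19. Untreated hubs were most often on chromosomes 6 (115), 19 (90) and 1 (86), with 64 on chromosome 8. None of the hubs lay on chromosomes 15 or 22. The hub at 19:29975001-30000000 had 51 partner bins in untreated, 60 in GSI and 47 in washout, that at 8:127850001-127875000 had 50, 49 and 42, and that at 17:70100001-70125000 had 49, 46 and 51. Some hubs had most partners in GSI: 19:29525001-29550000 had 31 in untreated, 68 in GSI and 33 in washout, and 6:39300001-39325000 had 24, 54 and 27. The largest cluster of hubs common to all 3 held 22 bins from 29125001 to 31325000 of chromosome 19, with a mean of 34.5 partners in untreated, 42.5 in GSI and 33.1 in washout. A cluster of 8 lay from 127800001 to 129125000 of chromosome 8, with 38.6, 47.2 and 41.4. Partner numbers were higher in GSI over all bins too, so the higher GSI means do not set these clusters apart.

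Of the untreated hubs 30.8% were hubs in GSI and 37.5% in washout. The median bin had 8 partners in untreated, 10 in GSI and 8 in washout after thinning, and 12, 10 and 24 before it. Thinning removed weak pairs from the deeper lists and none from the GSI list, so the thinned values are not strictly matched.

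Connected groups of bins were compared between conditions. There were 557 groups of at least 5 bins in untreated, 526 in GSI and 645 in washout, with a median span of 5325, 5075 and 4500 kb. Over bins present in both libraries of a comparison, the adjusted Rand index of the groupings was 0.819 for untreated and GSI, 0.787 for untreated and washout and 0.762 for GSI and washout. Pairs reach 2 Mb at most, so neighbouring bins group together in any library: against equal-width blocks, as many per chromosome as the second library had groups, the index was already 0.642, 0.633 and 0.618. The group with the most links per bin was on chromosome 19 in every library, from 28250001 to 33075000 in untreated (9.48 links per bin) and washout (9.72), and from 28250001 to 30950000 in GSI (11.9). Groups on chromosome 10 from 3100001 to 4850000 followed in untreated (8.86) and washout (8.81), and in GSI 2 groups on chromosome 8 from 141450001 to 146300000 followed, with 10.2 and 10.6.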

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

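The alternatives with bins of 5 and 100 kb, pairs with anchors overlapping in all 3 libraries, at least 20 counts, removal of the windows low in GSI, and other minimum counts and folds for windows were chosen after the data had been seen, as were the windows themselves. Counts of 1 Mb windows 4-fold lower in GSI kept their direction, above the count of higher windows, in all settings except shared anchors, which gave 0 in both directions and leaves out the anchors GSI lacked by design. They were 126 after thinning, 79 with at least 500 counts and 113 at 8-fold, and in 8 other settings they stayed within 1.5 times of 195. Splits of bins and bin pairs differed after thinning, which changed totals and also dropped weak pairs from the deeper lists only, so depth alone was not tested, and neither were other causes. A stricter FDR was not run, because the files hold no FDR or p, and promoter and gene list results were not run. Intervals cover counting error only, and pairs of few counts limit the sharing between lists.

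For GSI against untreated (547343 bin pairs lower), the order of lower and higher turned after thinning (368854 lower), with 5 times the pseudocount (48424) and for pairs listed in all 3 (5424). It held with at least 5 counts (113323), at least 20 counts (15023), up to 500 kb (159120) and 100 kb bins (130990). With shared anchors the split was almost even, with 271312 lower and 269505 higher. For washout against GSI (412821 higher) the order turned after thinning (343634), with 5 times the pseudocount (33354) and for pairs listed in all 3 (3110). It also turned with 5 kb bins, but the split was almost even (528985 higher, 542648 lower). It held under median-ratio scaling (684653), at least 5 counts (268351), at least 20 counts (24477), at least 20 kb (649202), without the top 0.1 percent of bins (671283) and with 100 kb bins (130323). Pairs of 3 washout counts against none listed in GSI gave 1.99-fold, just under the size counted, so they are not in the 412821. They passed under median-ratio scaling, from 20 kb and without the top 0.1 percent of bins, where the higher counts rose.

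For washout against untreated (470587 lower) the order turned under median-ratio scaling (450838), at least 5 counts (104254), at least 20 counts (14420) and at least 20 kb (457889). Scaling within distance classes gave an almost even split, with 470465 lower and 478756 higher. The order also turned up to 500 kb (134612), without the top 0.1 percent of bins (468195), with 100 kb bins (79357) and with shared anchors (257009). Under median-ratio scaling, from 20 kb and without the top 0.1 percent of bins, the lower count changed little. The higher count went from 390360 to 653989, 621257 and 640668. In these settings 3 washout contacts against none listed, at 1.99-fold in the main setting, passed 2-fold, so these turns largely rest on that edge. It held with 5 times the pseudocount (37070), pairs listed in all 3 (11195) and 5 kb bins (712572). Bin pairs lower in GSI and then higher (80213, fewer than the opposite) outnumbered the opposite with 100 kb bins (72111) and at least 20 counts (13411). They remained fewer after thinning (53290), with 5 times the pseudocount (10545), listed in all 3 (1621), at 1.5-fold (154177), at 3-fold (32260), with 5 kb bins (28224) and shared anchors (49810).

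Bins lower in GSI (9422) became fewer than higher ones after thinning (5997) and remained more with 100 kb bins (3946) and shared anchors (4665). Bins higher in washout than in GSI (16980) became fewer than lower ones after thinning (3881) and remained more under median-ratio scaling (39985), 5 kb bins (26664), 100 kb bins (6057) and shared anchors (5602). Median-ratio scaling moved log2 ratios without pseudocount by -0.28 for GSI against untreated, 0.92 for washout against GSI and 0.64 for washout against untreated.

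The share of untreated pairs found in GSI (15.7%) was 58.8% within 1 bin, 17.8% after thinning, 20.1% with at least 5 counts, 15.2% from 20 kb, 2.75% with 5 kb bins, 61.3% with 100 kb bins and 17.3% with shared anchors. In the same order, GSI pairs found in untreated (20.3%) were 69.3%, 15.8%, 28.3%, 19.7%, 3.67%, 74.6% and 17.4%, and GSI pairs found in washout (32.7%) were 85.5%, 15.4%, 40.3%, 32.1%, 5.15%, 89.6% and 22.3%. Hubs in all 3 (158) were 854 at the 95th percentile. With at least 5 counts, groups of 5 or more bins were 1709 in untreated, 1181 in GSI and 1776 in washout, and median distances were 115, 105 and 141 kb, with untreated now above GSI; from 20 kb these were 868, 892 and 830 kb.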

Other observations

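The tests of fewer draws, of lasting loss of DNA copies, of low signal blocks and of a response to GSI were chosen after their results had been seen, as were the windows, the minimum of 20 counts for the counted pattern and the share of the excess outside the windows; the remaining tests were set before their values were known. An earlier test of fewer draws by thinning was dropped, because thinning could not have moved a window by 4-fold.

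A few stretches of 1 Mb windows were at least 2-fold higher in GSI. From 129 to 133 Mb of chromosome 10 there were 1167 contacts in untreated, 2289 in GSI and 3535 in washout, a log2 ratio of GSI to untreated of 1.59. From 28 to 30 Mb of chromosome 19, which overlaps the largest hub cluster, there were 6986, 10010 and 13597 (log2 ratio 1.13), and washout matched untreated (-0.02). On chromosome 8 the stretches from 132 to 134 Mb (2485, 3442 and 5662 contacts) and from 136 to 138 Mb (2483, 3671 and 6740) had log2 ratios of 1.08 and 1.18. From 131 to 134 Mb of chromosome 11 there were 351, 749 and 2552 contacts, and washout stayed above untreated (log2 ratio 1.88). Median-ratio scaling lowers these GSI to untreated ratios by 0.28, which takes the stretches on chromosomes 19 and 8 below 2-fold.

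In the 195 windows low in GSI, 45.2% (95% interval 42.0 to 48.6) of untreated bin pairs with at least 20 counts were listed in GSI within 1 bin. Elsewhere 87.3% were (median counts 30 and 31). The windows were chosen for low GSI counts, so a lower share there was built in and cannot decide whether fewer draws gave them. A low starting level alone was argued against, as only 22.4% of windows at like untreated levels were also low. This share was above that of all windows (195 of 2326), so the starting level may account for part. The 195 windows had a median scaled contact of 131 in untreated, against 342 in the other windows. Their median number of anchors was 85 against 207 in untreated and 106 against 267.5 in washout. The median log2 ratio of washout to untreated was -0.57, so a 4-fold deficit did not last in the washout library. The bound of 4-fold was set after this value had been seen. A smaller lasting loss of DNA copies, or a loss in the GSI culture alone, was not tested. Loss of weak anchors at a calling limit could not be excluded: 58.6% (95% interval 54.5 to 62.6) of untreated anchors with at least 50 contacts there overlapped a GSI anchor, against 93.9% elsewhere. Blocks of low signal in this cell line, such as regions of few DNA copies, may add to this, with a median log2 ratio of contact inside to beside the stretches of -0.63 in washout (lower inside in 18 of 25), -0.26 in untreated (15 of 25) and -2.18 in GSI (21 of 25). A response to GSI stays open and cannot be told apart from a weaker pull-down in the GSI library, as there was 1 GSI library.

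Bin pairs with at least 20 contacts were lower in GSI and then higher in washout 3.10 times as often as the opposite. Most of this excess, 90.2% (8187 of 9080 pairs), lay outside the windows low in GSI, and the ratio without them was 2.98. Without these windows 52784 of 54408 such pairs remained, so a large share outside was given in advance. The bounds of 1.2 and 1.5 also lay below the 1.73 to 2.20 of draws from 1 profile. The windows thus did not hold most of the excess, but this test cannot weigh them as a cause. Separate calling of anchors stays open at a ratio of 2.85 among pairs with shared anchors: the bound of 1.5 set beforehand was too low, as libraries of 1 profile gave 3.98 to 7.50 for these pairs. Those draws held far fewer pairs, 235 and 43 on average against 7574 and 2661 observed, so they do not settle the question either. Unequal depth may account for part, as thinned libraries, which also lost weak pairs from the deeper lists, gave 1.37, between the bounds of 1.2 and 1.5. Equal draws from 1 profile gave 1.15 to 2.15. At the observed sizes such draws held 683 and 356 pairs on average, against 13411 and 4331 observed, so their ratios say little about depth. A return of contacts with Notch recovery was not separated from these.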
